A study of Mus musculus with 2 samples.

How the data were processed

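RNA was measured in 2 mouse colon lamina propria libraries, 1 Control and 1 K14/hyal1. Per the labels' protocols, RNA was extracted with a PureLink RNA Mini Kit, libraries were made with a TruSeq Stranded mRNA kit, which selects polyadenylated RNA, and sequencing was done on an Illumina HiSeq instrument. Partek and the mm10 build are named in the submitters' processing notes; the aligner, the counting rule, the use of strand and the versions are not given in the sources used here.

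The main values were a deposited table of normalized counts with 72178 transcript rows and 27874 gene symbols. The unit is not named in the file headers; the deposited values were read as CPM, because low values of each library were multiples of 1 constant step, 0.0164 in Control and 0.0345 in K14/hyal1, which is what 1 read would be worth if 61105084 and 29020439 reads had been scaled to a total of 1000000. The authors' columns summed to 416434 and 475975, so only part of the scaled reads is in the table. An offset of 0.0001 in each deposited row was taken off, and rows were summed by symbol. Of gene values up to 300 reads, 81.6% in Control and 82.9% in K14/hyal1 lay within 0.1 of a whole number of reads, and 36.3% and 37.5% of transcript values did, so reads are called estimated and no count test was run. The authors also deposited a gene table of 15869 rows with a least-squares mean CPM, a ratio, a signed fold change, p-values and false discovery rates; the model behind the deposited p-values is not given in the sources used here. Its total signal per gene, per the file headers a total of counts, covers more libraries than these and was not used. A further deposited table, headed as a fold change with p-values on the mm10 transcriptome, was examined but entered no comparison, because the other unit it holds is not a fold change: the column had a Spearman correlation of 0.954 with the K14/hyal1 level and 0.101 with the ratio across 14860 genes, and 96.9% of its p-values were 1 repeated value. A sheet on skin was not used here.

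With 1 library per group there was no test, no standard error and no p-value. The log2 ratio was log2((K14/hyal1 + 1)/(Control + 1)) in CPM, which understates differences of low genes; folds in the text are plain ratios of CPM, while members named highest or lowest were ranked on the log2 scale. A gene passed the filter when its mean was at or above 2.31 CPM, the median of the 27125 symbols above 0 in a library, and it was counted as different at 2-fold on the log2 scale. Intervals were exact 95% Poisson (levels) and Clopper-Pearson (ratios) intervals from estimated reads, for counting error only, since reads without molecular identifiers are not independent molecules; the floor was 3 reads. Gene lists, 36 in all, were fixed before the data were examined; the 29 with at least 5 members past the filter were described by their median and its percentile among 10000 random lists matched on mean expression in 20 bins. A list stood apart at or below percentile 2.5 or at or above 97.5, as a description of these libraries.

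The genes named were fixed by rule before the data were examined: Hyal1 and Krt14; the 12 largest and 12 smallest log2 ratios past the filter, without predicted or clone names and immunoglobulin or T cell receptor segments; in each list that stood apart, the 3 members furthest in the direction of the median and the 1 furthest the other way; in other lists the highest and the lowest; and in lists with fewer than 5 members past the filter, those members. Some genes that the rule selects are not reported here. Predicted or clone names were 85 of the higher and 42 of the lower genes, and 2 immunoglobulin segments passed the filter, both higher. Coordinates are those of GENCODE M21 on mm10, matched by symbol for 95.9% of symbols. Alternatives were other pseudocounts, filters, fold thresholds, scalings (the median gene, TMM, totals without the 20 most abundant genes), the gene table, other list summaries and, added after the data were seen, removal of the trend with GC content or transcript length by a running median over 501 genes.

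The steps were tested on simulated data for K14/hyal1 against Control. Both simulated libraries were Poisson draws from the Control levels, with no spread between animals or libraries. The counts below therefore cover counting error only and give no false call rate for the real pair. Of 13065 unchanged genes, 0 were called at 2-fold; of genes simulated at 1.5-, 2-, 4- and 8-fold, 0 of 48, 7 of 47, 45 of 45 and 44 of 44 were called among 13269 genes run. A list of 20 genes planted at 1.5-fold was at percentile 100, and 96.2% of 654 ratio intervals held the true ratio. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.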

Results

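Poly(A)-selected RNA from the colon lamina propria, the connective tissue layer under the gut epithelium, was sequenced from C57BL/6J mice of 2 genotypes. Epithelial transcripts were also abundant in both libraries, as given below, so the material was not connective tissue only. One genotype was control. The other, K14/hyal1, is named for the keratin 14 promoter, which is active in the basal layer of the skin, and for Hyal1, an enzyme that cleaves the matrix polysaccharide hyaluronan. The title of the study concerns inflammatory exchange between epithelia through fibroblasts and hyaluronan, so the comparison asks how the colon of K14/hyal1 mice differs from that of control mice. Each genotype had 1 library, so no difference below has a replicate check: each is a difference between 2 libraries, not between 2 genotypes. The estimated reads in the table were 25446232 for Control and 13813007 for K14/hyal1, and 3 reads were worth 0.0491 and 0.103 CPM, the unit in which all levels are given (reads scaled to a library total of 1000000). Intervals in brackets are exact 95% intervals for counting error only.

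Hyal1 itself was at a similar level in both colon libraries. It had 3.36 CPM in Control (2.91 to 3.85, 205 estimated reads) and 3.77 CPM in K14/hyal1 (3.08 to 4.53, 109 estimated reads), a ratio of 1.12 (0.879 to 1.42). The gene lies on chromosome 9 at 107576927-107581710 (mm10). Krt14, the keratin whose promoter names the line, on chromosome 11 at 100203162-100207548, had 0.507 CPM in Control and 0.517 CPM in K14/hyal1, a ratio of 1.02 (0.511 to 1.94), below the expression filter in this tissue. The log2 ratio of Hyal1 was 0.13, and it was -0.05 and -0.02 after scaling to the median gene and after TMM scaling, so its sign was not fixed by these data. Whether these values would register the transgene's transcript was not analysed here.

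Plasma cell, stromal and non-polyadenylated transcripts led the genes that were higher in the K14/hyal1 library, and a small set of secretory gland genes and clock genes led those that were lower. Of 13563 genes past the filter, 509 were at least 2-fold higher and 209 at least 2-fold lower in K14/hyal1, so that 70.9% of these differences were higher. The median log2 ratio of all genes past the filter was 0.21, and the higher share was 46.2%, 51.0% and 54.4% after scaling to the median gene, by TMM, and to totals without the 20 most abundant genes. Of the 509 higher genes, 300, 328 and 347 stayed at least 2-fold higher under these scalings. Group medians below are therefore read against matched random lists, which carry the same shift. The correlation of log2 values across genes between the libraries was 0.935 (Pearson; genes are not independent replicates).

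**Figure D1:**
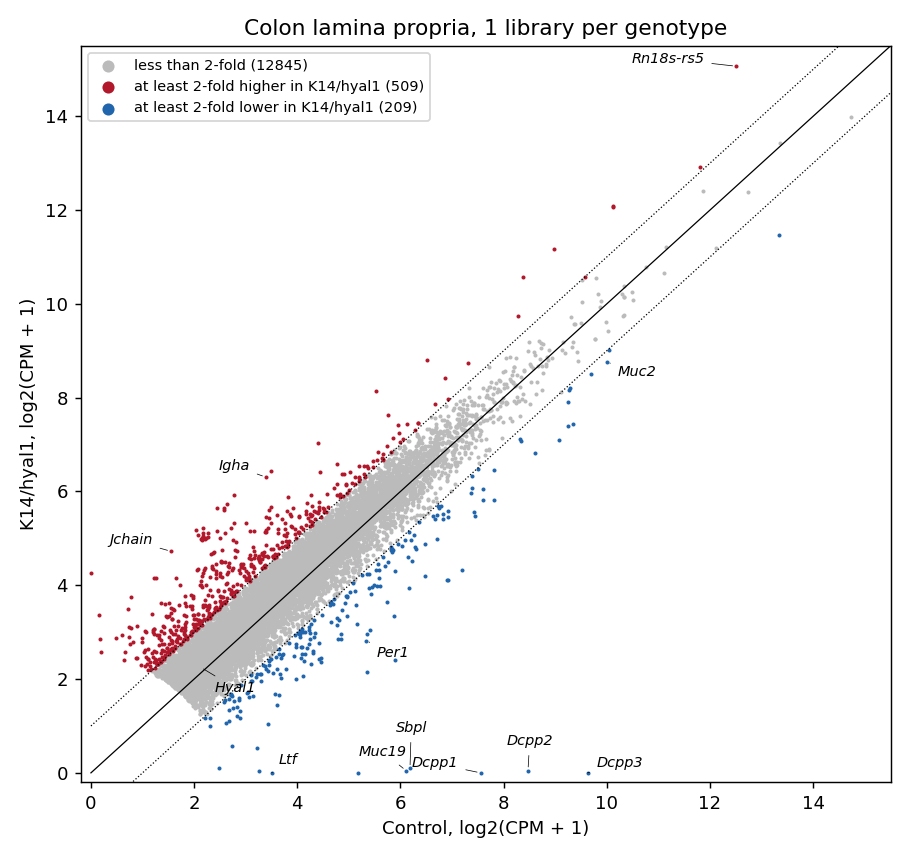
Each point is 1 of 13563 genes past the expression filter, with log2(CPM + 1) of the Control library on the x axis and of the K14/hyal1 library on the y axis. The solid line marks equal values and the dotted lines 2-fold differences; 509 genes are higher (red) and 209 lower (blue), with Dcpp3 at 790 CPM in Control and 0 in K14/hyal1.

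Immunoglobulin constant genes were among the largest differences. Ighg2b, the heavy chain of IgG2b, was at 0.115 CPM in Control and 9.34 CPM in K14/hyal1, a ratio of 81.5 (39.0 to 205). Igha, the heavy chain of IgA, had 9.48 CPM in Control and 78.1 CPM in K14/hyal1, 8.24-fold higher (7.52 to 9.05). Jchain, which joins IgA and IgM into polymers, was 13.2-fold higher (10.8 to 16.1) and the light chain gene Iglc2 17.7-fold higher (12.8 to 24.8). Immunoglobulin constant genes are closely related in sequence, and reads may have been split between them. The other leading genes were the small nuclear RNA genes Rnu2-10 (9.74-fold) and Rnu1a1 (10.2-fold), the ribosomal RNA entry Rn18s-rs5 (5.89-fold), the histone gene Hist2h2bb (6.70-fold), the leucyl-tRNA synthetase gene Lars2 (6.20-fold), the endothelial gene Mmrn1 (8.51-fold), the fibrillin gene Fbn1 (6.47-fold) and the matrix gene Spon2 (7.94-fold).

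At the low end, 5 secretory genes that sit together on chromosome 17 between 23880876 and 23955274 were abundant in Control and nearly without reads in K14/hyal1. Dcpp3 had 790 CPM in Control (783 to 797) and 0 reads in K14/hyal1, which is at least 7638-fold lower against a floor of 3 reads. Dcpp1 had 187 CPM and 0 reads, at least 1809-fold lower. Dcpp2 had 354 CPM and 1 estimated read, Sbpl 71.7 CPM and 2 estimated reads, and Sbp 8.55 CPM and 1 estimated read. The Dcpp genes are near-identical and Dcpp1 and Dcpp2 overlap in the annotation, so the share of reads given to each is uncertain. Muc19, a gel-forming mucin on chromosome 15, had 68.0 CPM and 1 estimated read, and Ltf, the iron-binding protein lactoferrin on chromosome 9, had 10.3 CPM and 0 reads, at least 100-fold lower. The authors' deposited table gives Ltf 0.0690 CPM in K14/hyal1. The remaining genes at this end were Per2, Per1 and Creb3l1, described below, the transcription factor gene Zbtb16 (5.70-fold lower, 4.95 to 6.59) and the nuclear receptor gene Ppard (4.94-fold lower, 4.47 to 5.48).

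Connective tissue genes were higher in the K14/hyal1 library as a group. The fibroblast list had a median log2 ratio of 0.99 over 27 members, 13 of them at least 2-fold higher and 0 lower, at percentile 100 of 10000 matched random lists. Pi16, a marker of adventitial fibroblasts, was 6.07-fold higher (4.89 to 7.59), Fbln2 4.49-fold (4.07 to 4.96) and the collagen-binding proteoglycan Dcn 3.73-fold (3.57 to 3.90), while Ly6a was 1.60-fold lower (1.48 to 1.74). The matrix list had a median of 0.80 over 30 members, 11 higher and 0 lower, also at percentile 100. Its highest members on the log2(CPM + 1) scale were Col14a1 (4.83-fold), the elastin gene Eln (4.26-fold) and the laminin gene Lama2 (3.36-fold), and Bgn was lowest at 0.924-fold. Blood and lymphatic endothelial genes had a median of 0.78, 7 of 22 higher and 0 lower, at percentile 100; the lymphatic genes Mmrn1, Reln (5.44-fold) and Lyve1 (4.24-fold) led them, and Robo4 was at 0.783-fold (0.579 to 1.05). With a pseudocount of 10 the fibroblast median was 0.59 and the endothelial median 0.28, and the endothelial median was 0.47 without a filter, 1.89 with the filter at a higher mean and 0.51 after scaling to the median gene. The values without the scaling stayed above the range of random lists, and the scaling shifts those lists as well. Smooth muscle genes did not stand apart, with a median of 0.20 over 25 members, 0 of them 2-fold different and a percentile of 54.5. Their extremes were Itga8 at 1.75-fold and Hspb6 at 0.580-fold.

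Macrophage genes were higher as a group, with a median of 1.44 over 16 members, 9 at least 2-fold higher and 0 lower, at percentile 100. The median was 0.94 without members of another list, 0.81 without a filter and 0.63 with a pseudocount of 10, each still above the range of random lists. Lyz2, which encodes lysozyme, was 4.07-fold higher (3.81 to 4.36), the mannose receptor gene Mrc1 3.83-fold (3.47 to 4.23) and Adgre1, which encodes F4/80, 5.53-fold (4.25 to 7.24), while Mertk was 1.41-fold lower (1.27 to 1.56). Complement genes had a median of 1.20, with 11 of 15 higher and 0 lower, at percentile 100, among them C1qb (4.14-fold) and C4b (3.68-fold), with Cfb at 1.13-fold. C1qb is also on the macrophage list; 3 complement genes are on another list. The 7 cytokine and chemokine genes past the filter had a median of 0.80 at percentile 99.9, with 1 higher and 0 lower. Ccl6 was 2.65-fold higher, and Cxcl12, Ccl28 and Cxcl13 had log2 ratios of 0.96, 0.83 and 0.02. The cytokine median was 0.39 with a pseudocount of 10, 0.14 without a filter and 0.50 after the GC trend was taken off, still above the range of random lists. MHC class II genes had a median of 0.62 at percentile 98.7, with 0 of 7 at 2-fold: H2-Ab1 was at 1.87-fold, H2-Aa at 1.73-fold, H2-Eb1 at 1.66-fold and Ciita at 0.994-fold. This list lost its place with the mean in place of the median (percentile 94.5). B cell and plasma cell genes were uneven: the median was 0.44 over 14 members at percentile 97.4, just inside the range of random lists, with 5 higher and 0 lower, from Ighg2b to Cr2 at 0.729-fold. The mean of this list, 1.09, was at percentile 100.

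Hyaluronan genes did not stand apart by their median, 0.38 over 15 members at percentile 92.8, but 5 of them were at least 2-fold higher and 0 lower. Lyve1, a hyaluronan receptor of lymphatic vessels, was highest on the log2 scale, and Has3, a hyaluronan synthase, was lowest at 0.916-fold (0.760 to 1.10). The other higher members, named after their values were seen, were the synthase gene Has2 (0.867 CPM in Control and 4.48 CPM in K14/hyal1), the proteoglycan gene Vcan (17.1 and 47.0 CPM), the scavenger receptor gene Stab1 (12.9 and 27.7 CPM) and the link protein gene Hapln1 (2.77 and 6.72 CPM). The mean of the list, 0.61, was at percentile 99.9. Fat cell genes had a median of 0.05 at percentile 8.58, with 3 of 15 higher and 0 lower; the fatty acid transporter gene Cd36 was 5.34-fold higher (4.56 to 6.27) and Cebpb was lowest at a log2 ratio of -0.77. Antimicrobial genes had a median of 0.14 at percentile 32.1, with 4 of 13 higher and 1 lower, from Lyz2 to Ltf.

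Absorptive and mucus-secreting epithelial genes were lower in the K14/hyal1 library relative to other genes. Colonocyte genes had a median of -0.34 over 27 members, 5 at least 2-fold lower and 0 higher, at percentile 0. The epithelial sodium channel genes Scnn1g and Scnn1a were 3.93-fold (3.26 to 4.78) and 3.37-fold (3.10 to 3.67) lower, the sodium-proton exchanger gene Slc9a3 4.67-fold lower (3.34 to 6.71), and Emp1 was 1.69-fold higher. With the filter at a higher mean the colonocyte median was -0.08, at percentile 1.54, and it was -0.19 without a filter, -0.57 and -0.53 after scaling to the median gene and by TMM, and -0.54 after the length trend was taken off. Goblet cell genes had a median of -0.20, 3 of 20 lower and 0 higher, at percentile 0.0400. Creb3l1 was 5.88-fold lower (5.08 to 6.83), and the mucin genes Muc2 and Muc3 were 2.35-fold (2.31 to 2.40) and 2.06-fold (2.03 to 2.10) lower, while Spink4 was 1.43-fold higher. The goblet median lay between -0.47 (length trend taken off) and -0.09 (highest with 1 member left out). General epithelial genes, chosen after their values were seen, had log2 ratios of 0.13 (Epcam, 371 and 407 CPM in Control and K14/hyal1), 0.16 (Krt8, 952 and 1062 CPM) and 0.21 (Krt19, 656 and 759 CPM). These were at or below the median of all genes, and scaling to the median gene made them -0.10, -0.08 and -0.02, so their sign was not fixed by these data. The levels of these 3 genes exceeded that of the fibroblast gene Dcn in both libraries (53.2 CPM in Control and 198 CPM in K14/hyal1), so both held much epithelial RNA. Enteroendocrine and tuft cell genes had a median of 0.50 at percentile 97.8, with 0 of 10 at 2-fold, and Dclk1 was at 1.87-fold, Chgb at 1.76-fold, Pyy at 1.75-fold and Chga at 1.03-fold. That call was lost under 7 alternatives. Crypt stem genes had a median of 0.26 at percentile 64.1 with 0 of 17 at 2-fold, between Slc12a2 (1.61-fold) and Prom1 (0.638-fold).

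Cell cycle genes were higher together. Their median was 0.92 over 28 members, 10 higher and 0 lower, at percentile 100, among them the mitotic kinesin gene Kif11 (3.12-fold, 2.76 to 3.52), the topoisomerase gene Top2a (2.65-fold, 2.45 to 2.85) and Cdk1 (2.80-fold, 2.36 to 3.33). Mki67, the proliferation antigen, was at 1.17-fold (1.13 to 1.21). With a pseudocount of 10 the cell cycle median was 0.40, still above the range of random lists. Ribosomal protein genes had a median of 0.68, 5 of 39 higher and 0 lower, at percentile 100, among them Rps14 (2.71-fold), Rps3 (2.44-fold) and Rpl5 (2.19-fold). Their median was 0.45 after scaling to the median gene and 0.36 after the length trend was taken off, the latter still above the range of random lists. Mitochondrially encoded genes were lower, with a median of -0.92, 6 of 15 lower and 0 higher, at percentile 0. The complex I genes mt-Nd4 and mt-Nd5 were 3.94-fold (3.81 to 4.08) and 3.62-fold (3.51 to 3.73) lower and mt-Atp8 3.12-fold lower, while mt-Nd3 was at 0.944-fold. Beside these groups, histone transcripts that lack a poly(A) tail were also higher in K14/hyal1, with a median of 1.87 over 65 genes, a set formed after the values were seen.

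**Figure D2:**
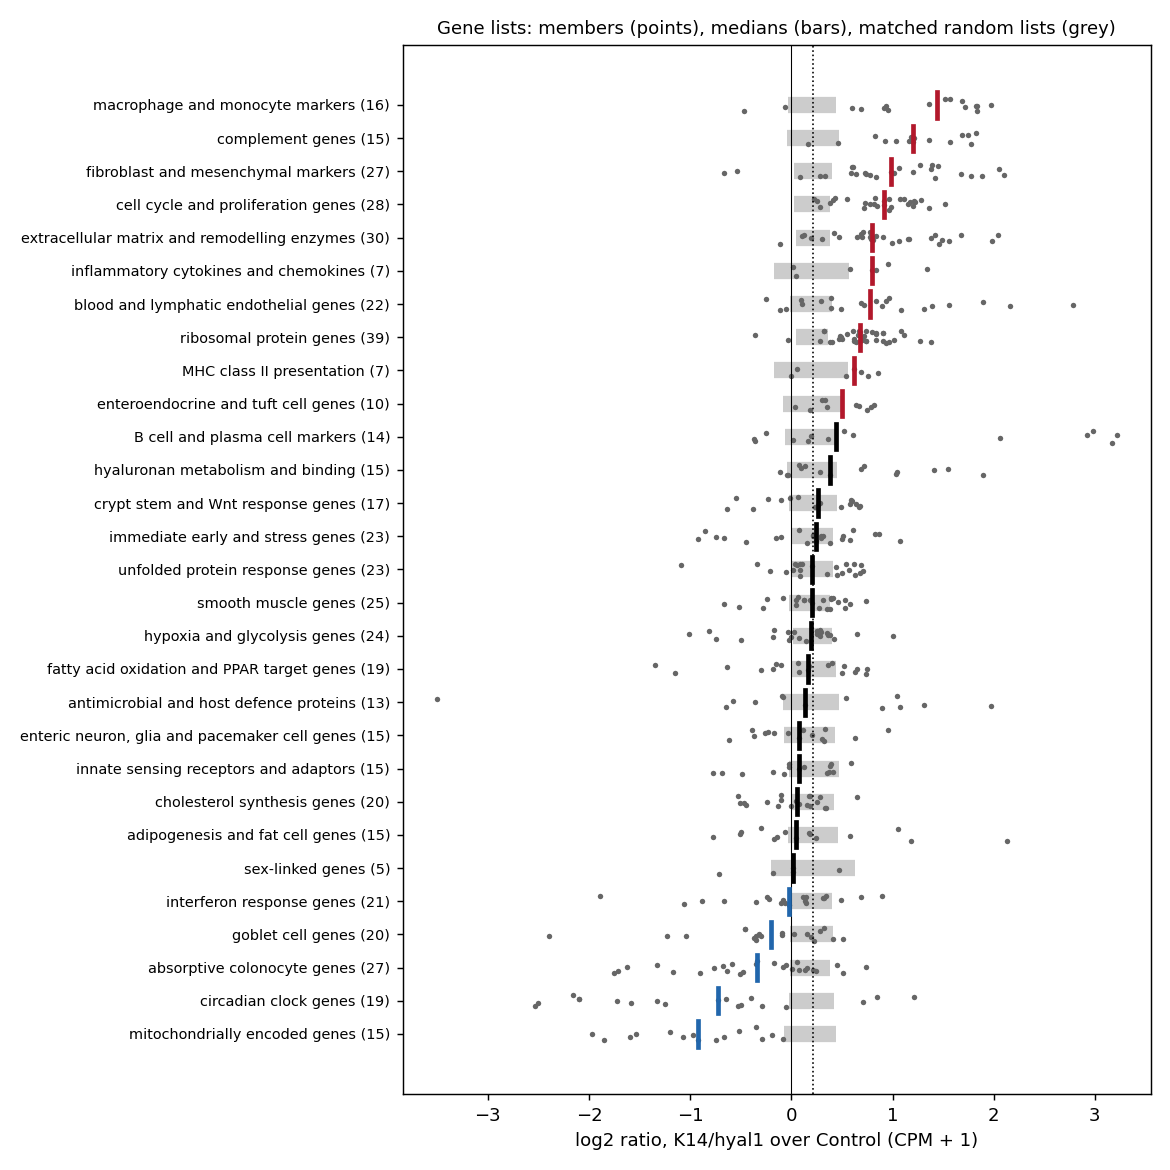
Each grey point is the log2 ratio (K14/hyal1 over Control, CPM + 1) of 1 list member past the filter, with the number of members in brackets; bars are list medians, red or blue where they lay outside the central 95% of 10000 matched random lists (grey bands). The dotted line is the median of all genes, 0.21; macrophage genes have a median of 1.44 and mitochondrially encoded genes of -0.92.

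Circadian clock genes differed strongly and in both directions. The list had a median of -0.72 over 19 members, 9 at least 2-fold lower and 1 higher, at percentile 0. Per2, a repressor of the clock loop on chromosome 1 at 91415982-91459324, had 57.8 CPM in Control and 9.13 CPM in K14/hyal1, 6.33-fold lower (5.59 to 7.20). Per1, on chromosome 11 at 69095217-69109960, was 6.46-fold lower (5.54 to 7.57) and Ciart, another repressor, 6.47-fold lower (4.85 to 8.80). Arntl, the activator that drives these genes, went the other way, with 4.81 CPM in Control and 12.5 CPM in K14/hyal1, 2.59-fold higher (2.22 to 3.03). With the filter at a higher mean the clock median was -1.25. The time of day at which the tissue was taken is not given in the sources used here.

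Interferon response genes were slightly low relative to other genes, with a median of -0.02 at percentile 2.01, 2 of 21 lower and 0 higher. Zbp1, a nucleic acid sensor, was 4.94-fold lower (3.82 to 6.49), Oasl2 2.58-fold lower and Ifit3 at a log2 ratio of -0.88, and Iigp1 was the highest at a log2 ratio of 0.89. After the length trend was taken off, the list was at percentile 5.27. Innate sensing genes had a median of 0.07 at percentile 11.8 with 0 of 15 at 2-fold, from Tlr2 (1.63-fold) to Ticam1 (0.553-fold). Neuron and glia genes had a median of 0.08 at percentile 20.8 with 0 of 15 at 2-fold; Vip had a log2 ratio of 0.95 and Nos1 of -0.62. Immediate early genes had a median of 0.24 at percentile 64.2, with 1 of 23 higher, Hsp90aa1 (2.15-fold), and 0 lower, the lowest being Fosb at a log2 ratio of -0.92. The cholesterol synthesis list was at 0.06 and percentile 6.72 with 0 of 20 at 2-fold, between Idi1 (1.61-fold) and Lss (0.683-fold). The fatty acid oxidation list was at 0.17 and percentile 30.6 with 2 of 19 lower and 0 higher, with Ehhadh at 1.75-fold and Ucp2 2.57-fold lower. Unfolded protein response genes were at 0.21 and percentile 50.6 with 1 of 23 lower and 0 higher, with Pdia6 at 1.67-fold and Syvn1 2.30-fold lower. Hypoxia genes were at 0.20 and percentile 45.6 with 1 of 24 higher and 1 lower, Adm (2.65-fold higher) and Epas1 (2.03-fold lower). Sex-linked genes had a median of 0.01 at percentile 17.0; Ddx3y, a Y-linked gene, had 27.1 and 37.9 CPM, and Xist 3.71 and 1.86 CPM. In all, 10 of 29 lists stood apart on the high side and 5 on the low side, where 1.45 would do so if genes were drawn independently. Genes of 1 list can vary together and some lists share members. The 1.45 is therefore not the number expected between 2 colon samples, and the excess over it is only a description.

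Blood cell and off-tissue markers were mostly below the filter, in 7 lists with fewer than 5 members past it. Of the 3 hemoglobin genes past the filter, Hbb-bs was 4.94-fold higher in K14/hyal1 (3.97 to 6.18), while Hba-a2 (2.25-fold) and Hba-a1 (1.86-fold) had log2 ratios of 0.83 and 0.68, below the 2-fold criterion. Of the neutrophil list, Ly6g was 2.14-fold lower (1.97 to 2.33), with 49.5 CPM in Control and 23.1 CPM in K14/hyal1, and Ltf was lower as above. The 18 members below the filter had at most 0.221 CPM in Control and 1.10 CPM in K14/hyal1. The Ly6g level was thus far above theirs and is not read as a neutrophil difference. Among those 18, named after their values were seen, Mmp9 had 0.221 and 1.10 CPM in Control and K14/hyal1 (13 and 32 estimated reads) and Csf3r 0.139 and 0.665 CPM (8 and 19 estimated reads). Their log2 ratios of 0.78 and 0.55 were below the 2-fold criterion on the log2(CPM + 1) scale, which understates differences at such low levels. By the plain CPM ratio both were more than 2-fold higher in K14/hyal1, from few reads. Of the T cell and innate lymphocyte list, 27 members were below the filter. Kit, from the mast cell list, was at 1.16-fold. Squamous genes past the filter were Sbsn (1.94-fold), Perp (90.5 and 90.6 CPM) and Sfn (0.904-fold). Skeletal muscle genes Acta1, Ckm and Tnni1 were at 1.08-, 1.33- and 1.31-fold, and the pancreatic list members Cela1, Clps and Sycn at 1.98-, 1.43- and 1.16-fold.

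Some of the stromal, mucin, immunoglobulin and clock genes above also pass the false discovery rate of the authors' deposited table, and others do not. Dcpp1, Dcpp2, Dcpp3, Sbpl, Sbp and Muc19, which led the lower end, have no false discovery rate in it. The authors' deposited table lists 359 genes at a false discovery rate of at most 0.05, 239 higher and 120 lower in K14/hyal1. Of these, 124 higher and 76 lower genes in the authors' deposited table were also at least 2-fold different here. Its ratios equalled those computed here within 0.1% for 90.0% of 15867 genes, since both come from the same libraries. In the authors' deposited table the false discovery rate was 6.53e-15 for Dcn, 3.09e-47 for Muc2, 3.53e-05 for Per2 and 2.09e-07 for Igha. In the authors' deposited table it was 0.9998 for Hyal1, Ighg2b and Ltf, 0.366 for Iglc2, 0.4285 for Pi16, 0.425 for Ciart and 0.836 for Arntl; with 1 library per genotype, these values do not measure the spread between mice.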

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

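Alternatives on GC content and length were chosen after the data were seen; the others before. No paired analysis was possible because each genotype had 1 library. Against 509 higher and 209 lower genes, the counts were 126 and 76 with a pseudocount of 10, 255 and 129 with the filter at a higher mean, 2401 and 663 at 1.5-fold, 73 and 29 at 4-fold (both by construction), 300 and 350 after scaling to the median gene, 328 and 315 after TMM, 302 and 325 without the GC trend and 273 and 357 without the length trend, which shift all genes down; the gene-level table gave 293 higher, over fewer genes. The scalings shift random lists as well and so say little about list places. Under the other alternatives 291 of the list results kept theirs, and with a pseudocount of 0.1 each of the 29 lists did. The B cell list moved outside the random range at 0.36 (pseudocount 10), 1.34 (higher filter), 0.24 (GC), 0.23 (length), 1.09 (mean), 0.52 (without shared members) and 0.52 (highest with 1 member left out), and the hyaluronan list at 0.31 (pseudocount 10), 0.38 (length), 0.61 (mean) and 0.54 (1 member left out). The neuron and glia list did so at -0.067 without a filter. The enteroendocrine list moved inside the range at 0.19 (pseudocount 10), 0.19 (no filter), 0.24 (GC), 0.18 (length), 0.49 (mean), 0.50 (unmatched lists) and 0.35 (lowest with 1 member left out), the interferon list at -0.19 (length) and 0.045 (1 member left out), and the MHC class II list at 0.32 (length) and 0.50 (mean). The cause was not tested. Among genes past the filter, the Pearson correlation of the mm10 column on the log2 scale was 0.845 with the Control level and 0.0514 with the ratio. Hyal1 and Krt14 stayed within counting error in every alternative run; Krt14 has no value in the gene-level table. Of the log2 ratios of named genes, 402 stayed within counting error and 316 moved beyond it. The K14/hyal1 library held fewer reads, so 3 reads were worth 0.103 CPM there and 0.0491 in Control.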

Other observations

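The tests of cell share, clock phase, depth, locus and salivary genes were chosen after the result was seen, and the histone and short RNA groups were formed after their members had been seen. The tests of the GC and length trends, glucocorticoid genes and male accessory gland genes were also added after the data were seen, but before their own results were.

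RNAs that carry no poly(A) tail were higher as a group in the K14/hyal1 library. Of 65 replication-dependent histone genes past the filter, 61 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.87, at percentile 100 of matched random lists. Of 14 small nuclear and other short non-coding RNAs, 12 were higher and 0 lower, with a median of 2.20. Rn7sk, which holds back transcription elongation, had 3591 and 7750 CPM in Control and K14/hyal1, Rpph1, the RNA of ribonuclease P, 331 and 1520 CPM, and Rmrp 308 and 852 CPM. The library kit selects polyadenylated RNA, so these levels also reflect what each library carried past that selection. Cell cycle genes were higher too, with a median log2 ratio of 0.92 at percentile 100. For the replication-dependent histone genes, a share due to proliferation was therefore not told apart from such carry-over.

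Higher stromal, macrophage and complement genes beside lower colonocyte and goblet genes formed the broadest pattern. If a lower epithelial share had raised all other cell types alike, fibroblast and smooth muscle genes would have moved together, but their medians differed by 0.78 (central 95% of random lists -0.24 to 0.30). The gap between fibroblast and colonocyte medians, 1.33, was 1.20 after the GC trend was taken off (random range -0.22 to 0.29) and 1.35 after the length trend was taken off (-0.24 to 0.28), which argues against either trend as the whole cause. What the dissection took, the non-polyadenylated RNA above and the genotype stay open, with 1 library each, and the genotype was not tested.

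Clock genes of opposite phases differed in opposite directions by their medians, though Npas2 (6.28 and 6.03 CPM) and Cry1 (5.45 and 3.14 CPM) of the Arntl phase were not higher. After the GC trend was taken off the clock median was -0.87 (random range -0.21 to 0.21), which argues against that trend. The median of 5 genes of the Arntl phase exceeded that of 11 genes of the Per and Dbp phase by 2.42 (random range -0.54 to 0.49), but these genes had been seen to differ, so this restates the pattern and the time of day at collection cannot be told apart from the genotype. As a hypothesis tested on genes not looked at before, 13 glucocorticoid response genes had a median log2 ratio of -0.37 at percentile 0.0100. At 2-fold, 2 were lower, Sgk1 (-1.46) and Mt1 (-1.14), and 0 higher. Of the 13, 6 were above 0, among them Tgm2 (0.56), Ddit4 (0.17) and Errfi1 (0.15). Only 1, Tgm2, was above the median of all genes, 0.21. A lower glucocorticoid response of some of these genes may be part of the clock pattern. The colonocyte and goblet lists were low against random lists too (percentiles 0 and 0.0400), so a low median alone does not identify that response. Time of day and glucocorticoids stay open beside the genotype, which was not tested, and glucocorticoids follow the daily cycle too.

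Of the 9 genes past the filter with at most 3 reads in K14/hyal1, 7 have established names: Dcpp1, Dcpp2, Dcpp3, Sbpl, Sbp, Muc19 and Ltf. Depth is excluded, since the lowest Control level was 82.7 times that of 3 reads in K14/hyal1, and so is loss of the chromosome 17 locus alone, since 2 of the genes lie on other chromosomes. Gland tissue in the Control sample stays open: of salivary gland genes with 10 reads, 42.9% (3 of 7) were at least 2-fold higher in Control by the plain CPM ratio and 1 on the log2(CPM + 1) scale, which genes under 1 CPM cannot pass, among them Aqp5 (2.07 and 0 CPM), while Amy1 (0.421 and 0.332 CPM) and Lpo (1.13 and 1.27 CPM) were not. Of male accessory gland genes, of which 1 (Spink1) is past the filter here, 75% (6 of 8) were by the plain ratio and 1 on the log2 scale, but the seminal vesicle secretory genes among them were scarce, as Svs5 with 0.638 CPM in Control against a median of 71.7 CPM for the 7 genes, a level requirement added after the values were seen, so neither source can be told apart from the other. The genotype was not tested, and no sort or gate is given.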
